A study of Mus musculus with 6 samples.

How the data were processed

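RNA from 3T3-L1 cells was extracted after 5 days of treatment, pooled from 4 replicate experiments per group, amplified and biotin-labelled, and hybridised to 1 Affymetrix Mouse Genome array per group, per the labels' protocols. The deposited table holds 45101 probe sets on 6 arrays, in log2 values between 2.17 and 15.01. The submitters' processing notes name RMA in Affymetrix Expression Console; version and settings are not given in the sources used here. RMA subtracts background, makes the arrays' distributions equal and summarises the probes of a set, so a shift shared by most genes of an array would be removed. Values near the upper end of the scale, as for Adipoq and Scd1, can be compressed.

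Probe sets were named through a table of the array platform's annotation, with symbols looked up by gene identifier. Of the probe sets, 34958 had 1 symbol, 932 had several and were not used, and 9211 were not listed in the table and are unnamed here, 51 of which are control probe sets. This gave 18193 genes. A gene was represented by its probe set with the highest mean over the 6 arrays, and 7455 of the detected genes had more than 1 probe set. A gene was called detected if its value reached the median of the table, 6.55, on at least 1 array; 12385 genes did. The table has no detection calls and this level is a convention, so the order of values under it is not relied on, and a fold that rests on one is uncertain. With values under the level raised to it, the genes at least 2-fold apart numbered 1251 for ritonavir against ethanol (519 higher, 732 lower), 203 for t10,c12-CLA against DMSO and 277 between the isomers.

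With 1 array per group, differences between groups were not tested, and the number of arrays limits the precision of each value. A test of the 4 arrays with ritonavir against the 2 without was not made here, since these arrays also differ in treatment and experiment. For 6 comparisons, and for the pair of arrays with ritonavir, the log2 difference of each detected gene was computed, and genes at least 2-fold apart were counted by direction. For 30 gene lists the median difference of the detected members was set against 10000 random lists of the same size, drawn within 20 bins of mean expression, and its percentile was taken, with 2.5 and 97.5 as bounds of the central range. Covariances of comparisons that share an array were set beside those of 100 simulations of unchanged arrays, and the number of shared genes beside the number independent sets would share.

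The comparisons, lists and alternatives were fixed before the data were examined, as was the rule for named genes, except for 3 alternatives added after seeing the data, which are named in the account of alternatives. The rule takes, per comparison, the 10 detected genes with the largest upward and the 10 with the largest downward difference of at least 2-fold, up to 2 members upward and 2 downward of each list, and Pparg, Cebpa, Adipoq, Lep, Slc2a4, Fasn, Scd1, Cpt1a, Ddit3, Ccl2 and Il6. Symbols of clone or accession type are counted but not named by it. The lists cover adipogenic transcription factors, mature adipocyte markers, lipid and cholesterol metabolism, mitochondria, insulin signalling, adipokines, stress responses, inflammation, interferon, matrix, cell cycle, proteasome, lysosome, hypoxia, drug metabolism, nuclear lamina, and markers of preadipocytes and of 5 other cell types. List members without a named, detected probe set did not enter. Among 870 named values, 82 had another detected probe set of opposite sign, 3 of them at least 2-fold, and 0 had a probe set 2-fold the opposite way.

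The alternatives were the mean of all probe sets of a gene, only probe sets without cross-hybridising suffixes, no detection filter or a stricter one at 8.77, quantile normalization again, removal of the trend of the difference on mean expression by lowess with a span of 0.3, thresholds of 1.5-fold and 3-fold, and the other ritonavir array or the mean of both. The counting and list steps were tested on simulated data for ritonavir against ethanol with 12385 genes. With the spread of the tenofovir and ethanol arrays, 50 of 50 genes changed 3-fold and 0 of 50 changed 1.5-fold were counted as 2-fold apart, and 0 of 12185 unchanged genes were. Of 20 simulated lists without a change 0 lay outside the central range, and of 20 shifted by 0.3 all did. At double that spread 3 of 20 lists without a change lay outside it, and 48 of 50 genes changed 3-fold were counted. The simulated genes varied independently of each other, so this does not show how often lists of genes that vary together would lie outside. The robust SD of the tenofovir and ethanol difference was 0.113, and even double that lies under the 0.314 between the arrays of ritonavir and of ritonavir with DMSO. How many unchanged genes would be counted at that larger spread was not simulated. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.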

Results

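Gene expression was measured in 3T3-L1 adipocytes, fat cells grown from a mouse preadipocyte line that matures in culture after hormonal induction. The cells were exposed for 5 days, during their maturation, to antiretroviral drugs or to drug combined with a fatty acid. In the first experiment they received ritonavir, an HIV protease inhibitor, at 20 µM, tenofovir, a nucleotide inhibitor of reverse transcriptase, at 1 µM, or ethanol at 0.1% as vehicle. In the second experiment they received ritonavir at 20 µM together with DMSO at 0.1%, or with 1 of 2 isomers of conjugated linoleic acid (CLA), c9,t11-CLA or t10,c12-CLA, each at 100 µM. The isomers differ in the position of their conjugated double bonds and in the order of the cis and trans bond. Each of the 6 groups was measured on 1 array with RNA pooled from 4 replicate experiments, so that no spread between replicates can be given. All differences below are single array differences on the log2 scale without a p-value, and "higher" and "lower" refer to the arrays compared.

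Of 18193 genes with a named probe set, 12385 reached the detection level on at least 1 array. The arrays had similar distributions, with medians between 6.54 and 6.56, which RMA brings about. Across all probe sets the tenofovir and ethanol arrays correlated at 0.998, and the c9,t11-CLA and DMSO arrays at 0.997. The correlation of the ritonavir and ethanol arrays was 0.973. The values of the 3' and 5' actin control probe sets lay between 0.19 and 0.54 apart on every array.

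**Figure D1:**
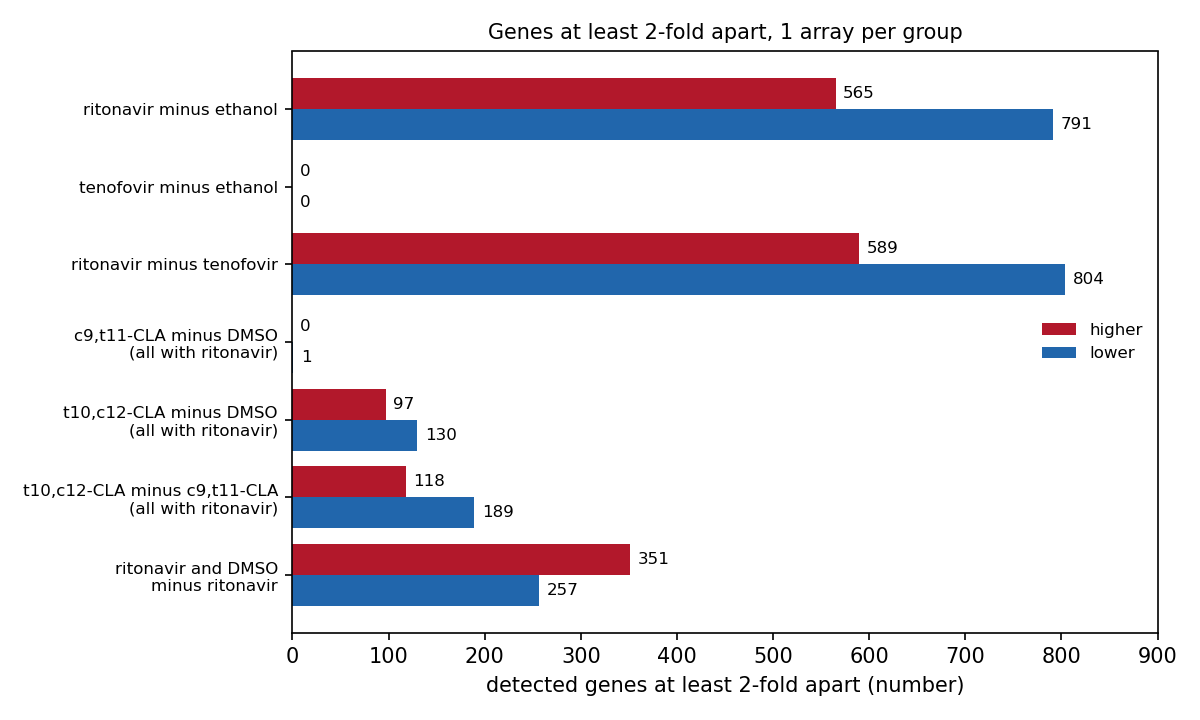
Number of detected genes at least 2-fold higher (red) or lower (blue) in each comparison, 1 array per group, with no error bars because no group has replicates. Ritonavir against ethanol gave 565 higher and 791 lower genes, tenofovir against ethanol gave 0, and the isomers differed from each other by 307 genes in total.

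The first comparison asked what ritonavir does to the transcriptome of maturing adipocytes. On the ritonavir array, many genes that mark fat cells were far lower than on the ethanol array. Retn, which encodes the adipokine resistin, was 95.2-fold lower, the lipid droplet gene Cidec 73.7-fold lower and Gpd1, a glycerol phosphate dehydrogenase of triglyceride synthesis, 56.7-fold lower. On the array of ritonavir with DMSO the log2 differences of these genes from ethanol were smaller, at -2.15, -1.04 and -1.44. Among the genes that were higher were the cytokine gene Il6, with a difference of 3.38, and Tagln, which encodes the actin-binding protein transgelin, with 3.77. In all, 565 genes were at least 2-fold higher and 791 at least 2-fold lower, together 10.9% of those detected.

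The 10 genes with the largest upward differences were Mlana (4.29), Fbln7 (3.89), Tagln, the smooth muscle actin Actg2 (3.49), the chemokine Ccl9 (3.47), Mreg (3.46), Il6, the cholesterol ester hydrolase Nceh1 (3.22), Trim30d (3.19) and Anxa3 (3.08). The largest downward differences were those of the melanocortin receptor accessory gene Mrap (-7.35), Retn (-6.57), the fatty acid receptor Ffar4 (-6.31), Cidec (-6.20), the carbonic anhydrase Car3 (-6.19), Gpd1 (-5.83), Pck1 (-5.57), Hcar2 (-5.52), Inhbb (-5.47) and Selenbp1 (-5.44). Mlana, Fbln7, Mreg, Il6, Mrap, Ffar4, Pck1, Hcar2, Inhbb and Selenbp1 lay under the detection level on 1 of the 2 arrays, and the exact size of their difference is uncertain. With values under that level raised to it, Mrap still differed by -5.86, Ffar4 by -5.38, Mlana by 3.38 and Il6 by 2.24.

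Transcription factors that drive adipocyte differentiation were lower. The master regulator Pparg differed by -2.49, Cebpa by -3.50 and Klf15 by -4.16, while Klf4 was 0.58 higher. Of 19 listed factors, 5 were at least 2-fold lower and 0 higher, with a median of -0.58. Of 19 detected mature adipocyte markers, 14 were at least 2-fold lower and 0 higher, with a median of -2.46. These included Adipoq, the gene of adiponectin, at -4.61 and the insulin-responsive glucose transporter Slc2a4 at -3.74. Lep, which encodes leptin, differed by -2.25 but ended under the detection level, and by only -0.38 against that level, which leaves 13 of the 14 markers. Among 16 adipokines and secreted factors, 10 were at least 2-fold lower and the median was -2.23, or 9 and -1.52 with values raised to the detection level. Haptoglobin (Hp) differed by -4.77 and Igfbp3 by 0.72.

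**Figure D2:**
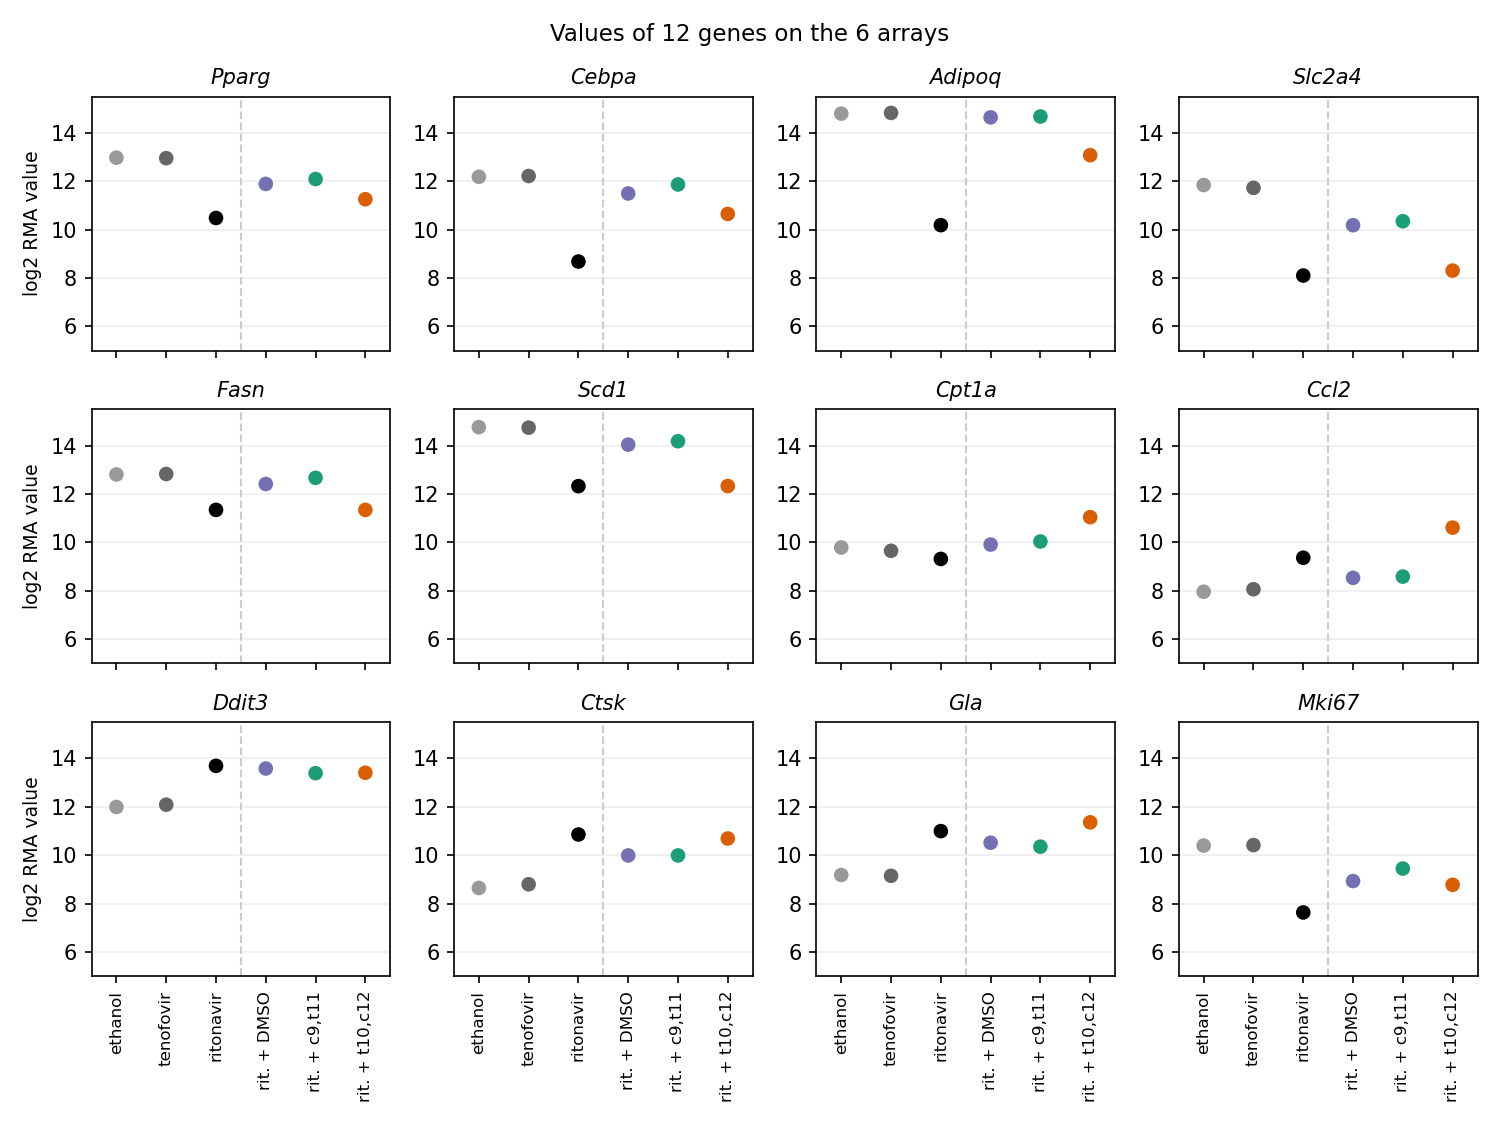
Log2 expression values of 12 genes on each of the 6 arrays, 1 point per array and no error bars. A dashed line separates the first experiment (ethanol, tenofovir, ritonavir) from the second, in which every array had ritonavir. Adipoq lay at 14.79 on the ethanol array, 10.18 on the ritonavir array and 14.64 on the array of ritonavir with DMSO, whereas Ddit3 lay at 11.99, 13.69 and 13.58.

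Lipid metabolism genes followed the same direction. The list for triglyceride synthesis, lipid droplets and lipolysis had 12 of 17 members at least 2-fold lower and a median of -1.70, with the hormone-sensitive lipase gene Lipe at -4.32 and Plin3 at 0.81. Fatty acid synthesis had 7 of 20 lower and a median of -0.83. Thrsp differed by -3.98 and ended under the detection level, Pnpla3 by -3.64, the fatty acid desaturase Scd1 by -2.44 and the fatty acid synthase Fasn by -1.46, while the elongase Elovl6 was 1.00 higher. On the array of ritonavir with DMSO, Thrsp differed from ethanol by -0.14, Pnpla3 by -2.56, Scd1 by -0.72, Fasn by -0.395 and Elovl6 by 1.02. Cholesterol synthesis and uptake had 11 of 20 lower and a median of -1.01, led by Pmvk (-2.04) and Insig1 (-1.60), with Ebp at 0.22. Fatty acid oxidation had 7 of 20 lower and a median of -0.62. Its members included Cpt2 at -1.66 and Acadvl at -1.47, whereas Pdk4, a kinase that restrains pyruvate oxidation, was 1.03 higher. Cpt1a, which controls fatty acid entry into mitochondria, differed by -0.47.

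Each of the 28 oxidative phosphorylation genes was lower, with a median of -0.45, although only Uqcrfs1 (-1.17) reached 2-fold. Mitochondrial DNA maintenance genes had a median of -0.02, between Rrm2b at 0.76 and Ppargc1b at -0.96. Brown and beige adipocyte markers had a median of 0.00 over 5 detected genes, of which Ppargc1a was 2.04 higher, and Cox7a1 (-4.40) and Cox8b (-2.18) were lower and ended under the detection level. Insulin signalling and glucose uptake had 7 of 19 members lower and 1 higher, the adaptor Grb14 at 1.59, and a median of -0.62, with Pde3b at -3.37. Hypoxia and glycolysis genes had 8 of 18 lower and a median of -0.79, with Egln3 at -3.67 and Ankrd37 at -3.39.

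Cell cycle genes had a median of -1.62, and 15 of 22 were at least 2-fold lower. The proliferation marker Mki67 and the centromere gene Cenpa both differed by -2.76, whereas Ccnd1, the gene of cyclin D1, was 2.05 higher. Inflammation, chemokine and cytokine genes split, with 8 of 18 higher and 4 lower and a median of 0.75. Csf1 was 2.53 and Ccl2, a monocyte chemoattractant, 1.40 higher, and the acute phase genes Lcn2 (-4.23) and Hp were lower. Among preadipocyte and fibroblast markers 8 of 20 were higher and 0 lower, with a median of 0.21. Tagln and the smooth muscle actin Acta2 (2.54) led this list, and Fgf10 differed by -0.68. The extracellular matrix list had 5 higher (4 with raised values) and 1 lower of 25 and a median of 0.02, with the crosslinking enzyme Lox at 1.67 and Col15a1 at -2.18.

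Lysosome and autophagy genes were higher as a group. Of 21 detected members 20 lay above 0 and 6 were at least 2-fold higher, with a median of 0.58. Ctsk, the gene of cathepsin K, was 2.21 higher and the galactosidase Gla 1.81 higher, while Tfeb, a regulator of lysosomal genes, differed by -0.90. The stress gene Ddit3 was 1.70 higher, as was Ppp1r15a at 1.03, yet the list for ER stress and the unfolded protein response had a median of -0.23, with Xbp1 at -1.81. ATF4 targets and amino acid response genes had a median of 0.37, with Aldh1l2 at 1.30, Atf3 at 1.11 and Ddit4 at -1.28. Interferon-stimulated genes had a median of 0.38, and Bst2 (2.32) and Ifit2 (1.69) were among the 5 that were at least 2-fold higher, while Cxcl10 differed by -1.39.

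Smaller group medians were seen for NRF2 targets and antioxidant genes (0.01), heat shock proteins (0.05), the proteasome (0.15), nuclear lamina and prelamin processing genes (-0.03) and xenobiotic metabolism and drug transport (0.15). Single members differed more, among them the small heat shock gene Cryab at 2.40, the drug efflux pump Abcc4 at 2.32, Cyp2f2 at -2.54, Taldo1 at -1.28, Psma1 at -1.35 and Tmpo at -1.05. Markers of other cell types gave no common direction. Macrophage markers had a median of 0.05 over 5 detected genes, with Cd68 at 1.83. Medians were -0.25 for endothelial, -0.11 for muscle, 0.09 for bone and cartilage and -0.40 for epithelial markers, the last with Krt19 at -2.45 and Krt18 at -2.12. Both keratin genes ended under the detection level, and against that level the differences were -1.96 and only -0.40.

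Against 10000 random lists matched on expression, the medians of the mature adipocyte, adipokine, lipid synthesis, cholesterol, cell cycle and hypoxia lists lay at percentile 0, and those of the lysosome and inflammation lists at percentile 100. These percentiles describe 1 pair of arrays. When the array of ritonavir with DMSO took the place of the ritonavir array, the count of genes at least 2-fold from ethanol was 558 in place of 1356. On that array, an alternative chosen after seeing the data for lists, medians were -0.58 for mature adipocyte markers, -0.59 for adipokines, -0.13 for cholesterol genes with 0 of 20 at least 2-fold lower, -0.19 for fatty acid synthesis, 0.12 for inflammation genes at percentile 89.3, 0.01 for oxidative phosphorylation and 0.16 for ER stress. The triglyceride and lipid droplet list had 3 of 17 at least 2-fold lower there and a median of -0.38, and fatty acid oxidation 0 of 20 lower and a median of -0.15. Matrix genes had 0 of 25 higher and 5 lower, with a median of -0.53, and preadipocyte and fibroblast markers 0 of 20 higher and 1 lower, with a median of -0.07.

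Tenofovir was compared with the same vehicle to ask whether another class of antiretroviral drug alters the cells. The tenofovir array was close to the ethanol array. No gene was 2-fold apart (0 of 12385), the largest upward difference was 0.84, the largest downward difference was -0.74, and 12 genes were at least 1.5-fold apart. Adipocyte genes had nearly equal values, with differences of -0.02 for Pparg, 0.03 for Cebpa, 0.03 for Adipoq, 0.16 for Lep, -0.12 for Slc2a4, 0.02 for Fasn and -0.02 for Scd1. Ddit3 and Ccl2 both differed by 0.10, Il6 by 0.15 with both values under the detection level, and Cpt1a by -0.14. Tenofovir can act on the mitochondrial polymerase, and the median of the mitochondrial DNA maintenance genes was 0.02, with Polrmt at -0.35, while that of oxidative phosphorylation genes was 0.04.

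In this comparison 9 of the 30 lists still had medians outside the central range of random lists, for example 0.06 for interferon-stimulated genes and -0.05 for ER stress genes. Why was not tested, and such percentiles are not read as an effect of tenofovir. The robust SD of all gene differences was 0.113, the smallest of the comparisons made.

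Ritonavir was also set directly against tenofovir. This comparison uses the same ritonavir array, and tenofovir and ethanol were close, so it repeats the picture against ethanol by construction and adds no further evidence. On the ritonavir array 589 genes were at least 2-fold higher and 804 lower than on the tenofovir array. Mrap (-7.37), Retn (-6.64), Car3 (-6.51) and Ffar4 (-6.29) had the largest downward differences and Mlana (4.53), Fbln7 (3.68) and Tagln (3.60) the largest upward ones. Mrap, Ffar4, Mlana and Fbln7 lay under the detection level on 1 of these arrays. Ahnak2, at 3.03, was among the 10 largest here. Medians were -2.43 for mature adipocyte markers, -1.62 for cell cycle genes and 0.55 for lysosome and autophagy genes. Across genes, which are not independent replicates, the ritonavir and tenofovir differences correlated at 0.04. Their covariance was 0.00372, against 0.00636 for simulated unchanged arrays with a shared control, so the shared ethanol array alone gives a covariance of that size or more.

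The array of ritonavir with DMSO serves as the control of the second experiment, and it was set against the ritonavir array of the first. Many adipocyte genes were much higher on the array with DMSO. Mrap differed by 5.49, Cidec by 5.16, Adipoq by 4.45, Retn by 4.42, Gpd1 by 4.38, Thrsp by 3.84 and Slc2a4 by 2.08. Among the lower genes were the smooth muscle actin Actg2 (-3.61), the myosin light chain Myl9 (-3.19), Tagln (-2.94), Fbln7 (-2.84), Lox (-2.45), Grem1 (-2.44) and Mgp (-2.41). Mrap and Thrsp lay under the detection level on the ritonavir array, and Actg2 on the array with DMSO. In total 351 genes were at least 2-fold higher and 257 lower.

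Mature adipocyte markers had a median difference of 2.08, with 12 of 19 at least 2-fold higher (11 with values raised to the detection level), and cholesterol genes had a median of 0.88. Cell cycle genes had a median of 0.74, and preadipocyte and fibroblast markers one of -0.76. Lysosome and autophagy genes had a median of -0.04, and Ddit3 differed by -0.11. DMSO was present only in the second experiment, so the vehicle and the experiment cannot be told apart. Whether ethanol was also present there is not given in the sources used here, so the vehicles compared are not fully known. Of the 1356 genes 2-fold apart between ritonavir and ethanol, 93.8% had the same sign when ritonavir with DMSO was set against ethanol, and 146 were again at least 2-fold higher and 306 again lower, where independent sets would share 8.58 and 23.6. Both differences subtract the same ethanol array, which builds in part of this. Their covariance was 0.267, against 0.00637 for simulated unchanged arrays with a shared control.

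The second experiment asked how the CLA isomers act in ritonavir-treated cells. A DMSO dose is recorded here for the control alone, so the differences between CLA and DMSO may include a difference in vehicle. With c9,t11-CLA the array was close to that of DMSO, and 0 genes were at least 2-fold higher and 1 lower. The 1 gene, AY036118, differed by -1.07 and is named here although it was chosen after its value was seen. Of the genes fixed beforehand, those detected lay between -0.55 (Il6, under the detection level on 1 array) and 0.37 (Cebpa). Pparg differed by 0.20, Fasn by 0.26, Scd1 by 0.14, Slc2a4 by 0.16, Cpt1a by 0.13, Ccl2 by 0.05, Adipoq by 0.04 and Ddit3 by -0.19. Lep lay under the detection level on every array of this experiment, and its differences are not given.

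Small differences ran in 1 direction within several lists. Of the 30 lists, 2 had medians below and 10 above the central range of random lists. As for tenofovir, such percentiles alone are not read as an effect. All 22 detected cell cycle genes were higher with c9,t11-CLA, with a median of 0.43, led by the mitotic kinase Plk1 (0.67) and Mcm6 (0.54). All 25 extracellular matrix genes were higher, with a median of 0.12 and Lum at 0.65 and Thbs1 at 0.42. Mature adipocyte markers had a median of 0.14, with Lipe at 0.57 and Car3 at 0.52. Adipogenic transcription factors, fatty acid synthesis and hypoxia and glycolysis genes each had a median of 0.11. Proteasome genes had a median of -0.08, with 27 of 30 lower. Cholesterol genes (0.01), oxidative phosphorylation genes (0.00), inflammation genes (0.01) and lysosome genes (0.01) had medians near 0. The robust SD of all gene differences, 0.136, was close to that between tenofovir and ethanol. With the mean of both ritonavir arrays as the control the count was 146 in place of 1, but that control brings in the array of the first experiment.

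With t10,c12-CLA, many lipid synthesis and adipocyte genes were lower than with DMSO, and some chemokine and fibroblast genes were higher. Thrsp, a regulator of lipogenesis, differed by -3.72, Gpd1 by -3.16, Retn by -3.02 and Scd1 by -1.71, while the chemokine Ccl2 was 2.07 higher and Cpt1a, which controls fatty acid entry into mitochondria, 1.13 higher. In total 97 genes were at least 2-fold higher and 130 lower. That is fewer than the 608 genes 2-fold apart between the arrays of ritonavir and of ritonavir with DMSO, which differ in experiment and vehicle. The count alone therefore does not set t10,c12-CLA apart from a difference between pools without CLA. The 10 largest upward differences were those of Serpinb9b (2.88), the chromatin protein gene Hmga2 (2.80), the proteoglycan Prg4 (2.64), the glutathione transferase Gsta2 (2.49), Prkg2 (2.45), Ctla2b (2.22), the matricellular gene Ccn1 (2.22), the chemokine Ccl8 (2.20), Tm4sf1 (2.12) and Procr (2.09). Beside Thrsp, Gpd1 and Retn, the largest downward differences were those of Mrap (-3.04), Sult1a1 (-2.61), Tmem182 (-2.41), the succinate receptor Sucnr1 (-2.30), Sema3g (-2.27), Fcor (-2.26) and Cidec (-2.21). Ctla2b and Sucnr1 fell short of 2-fold when values under the detection level were raised to it, at 0.94 and -0.97, while Thrsp still differed by -3.50 and Tmem182 by -1.93.

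All 20 cholesterol synthesis and uptake genes were lower, 9 of them at least 2-fold, with a median of -0.99, Idi1 at -1.56 and Pmvk at -1.41. Mature adipocyte markers had 9 of 19 at least 2-fold lower, or 8 with values raised to the detection level, since Pck1 lay under it on both arrays, and a median of -0.96, with Slc2a4 at -1.88 and Adipoq at -1.56. Fatty acid synthesis genes had a median of -0.66, with Acss2 at -1.78 and Fasn at -1.07. Triglyceride and lipid droplet genes had a median of -0.76, although the lipid droplet coat gene Plin2 was 0.74 higher, and G0s2 differed by -1.40. Adipokines had a median of -0.60, with Angptl4 at 1.13. Transcription factors differed less, with a median of -0.14, Pparg at -0.63, Cebpa at -0.85, Klf15 at -1.40 and Klf5 at 1.28. All 28 oxidative phosphorylation genes were lower, with a median of -0.34. Fatty acid oxidation had a median of -0.23, with Pdk4 at 1.21 and Echs1 at -0.98.

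Inflammation genes had 4 of 18 at least 2-fold higher and 8 of 18 below 0, with a median of 0.48, including Ccl7 at 1.98, and Il6 was 0.67 higher. Preadipocyte and fibroblast markers had 6 of 20 higher and 1 lower, with a median of 0.59, or 5 higher and 0 lower with raised values, since Ccn2 and Fap each lay under the level on 1 array. Heat shock genes had a median of 0.37, with Hspb1 at 1.11, and NRF2 targets had one of 0.27, with the cystine transporter Slc7a11 at 0.95 and Gclm, which acts in glutathione synthesis, at 0.92. In the matrix list Thbs1 was 1.70 and Timp1 1.54 higher. The macrophage marker Cd68 was 1.67 higher, whereas the macrophage list had a median of 0.16 over 5 detected genes. Cell cycle genes had a median of -0.05, although Ccnd1 was 1.40 higher, and Ddit3 differed by -0.18. With the mean of both ritonavir arrays as the control the count was 71 in place of 227, and the share of lower genes was 33.8% in place of 57.3%. That control also holds the array of the first experiment, so these values carry the difference between the ritonavir arrays.

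**Figure D3:**
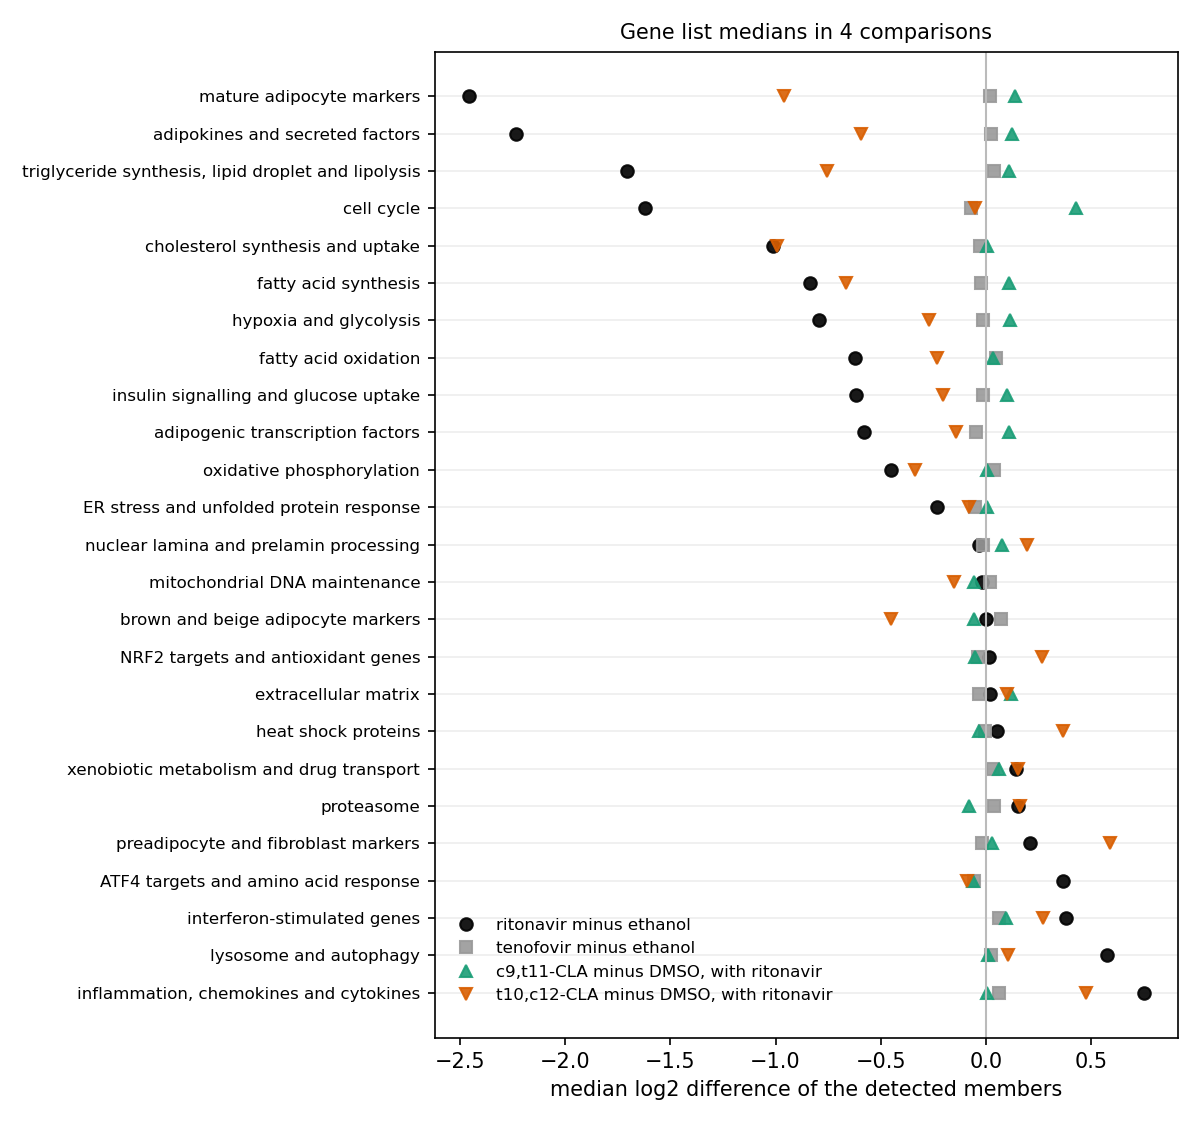
Median log2 difference of the detected members of 25 gene lists in 4 comparisons, 1 symbol per comparison; the 5 lists of other cell types are left out. Cholesterol synthesis and uptake lay at -1.01 for ritonavir and -0.99 for t10,c12-CLA, while cell cycle genes lay at -1.62 and -0.05 and at 0.43 for c9,t11-CLA. With ritonavir and DMSO against ethanol, which is not shown, the cholesterol list lay at -0.13.

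The isomers were given at the same dose and for the same time, and their arrays were compared directly. Adipocyte and lipid synthesis genes were lower with t10,c12-CLA than with c9,t11-CLA, and 118 genes were at least 2-fold higher and 189 lower. This too is fewer than the 608 genes 2-fold apart between the arrays of ritonavir and of ritonavir with DMSO. Thrsp differed by -3.69, Gpd1 by -3.51, Retn by -3.42, Mrap by -3.07, Sult1a1 by -2.82, Sema3g by -2.73, Car3 by -2.51, Slc2a4 by -2.04, Scd1 by -1.85, Adipoq by -1.60, Fasn by -1.33, Cebpa by -1.22 and Pparg by -0.83. Hmga2 (2.82), Serpinb9b (2.80), Gsta2 (2.73), Prg4 (2.64), Procr (2.31) and Prkg2 (2.26) were the detected genes with the largest upward differences above that level on both arrays. Thrsp ended under the detection level, and another probe set of it differed by 0.07.

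Cholesterol genes had 11 of 20 at least 2-fold lower and 0 higher, mature adipocyte markers 12 of 19 (11 with raised values) and a median of -1.19, and fatty acid synthesis genes 8 of 20 and a median of -0.62. Ccl7 was 2.06, Ccl2 2.02, Il6 1.22 and Cpt1a 1.00 higher, and 6 of 18 inflammation genes were at least 2-fold higher. Il6 lay under the detection level with c9,t11-CLA. Cell cycle genes had a median of -0.47, with Mki67 at -0.67, while Ccnd1 was 1.35 higher. For Ddit3 the isomers differed by 0.02. Lysosome genes had a median of 0.12 and ATF4 targets one of -0.09. Without replicates no interval can be put on these differences, and the small ones do not show that the isomers act alike.

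Finally the direction of the CLA differences was followed over the genes that were 2-fold apart between ritonavir and ethanol, a comparison that shares no array with them. Of the 791 genes lower with ritonavir, 82.2% were higher with c9,t11-CLA than with DMSO. The central range of matched random sets was 49.2% to 55.9%. The median difference was only 0.14, close to the robust SD of all gene differences in that comparison, 0.136. The same genes were higher with t10,c12-CLA in 15.8%, and their median difference was -0.43. Of the 565 genes higher with ritonavir, 67.6% were lower with c9,t11-CLA, with a median of -0.08, and 19.6% were lower with t10,c12-CLA, with a median of 0.30. With t10,c12-CLA 114 of the genes lower with ritonavir were again at least 2-fold lower, where independent sets would share 8.30, and 60 of the higher genes were again higher, where independent sets would share 4.43.

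**Figure D4:**
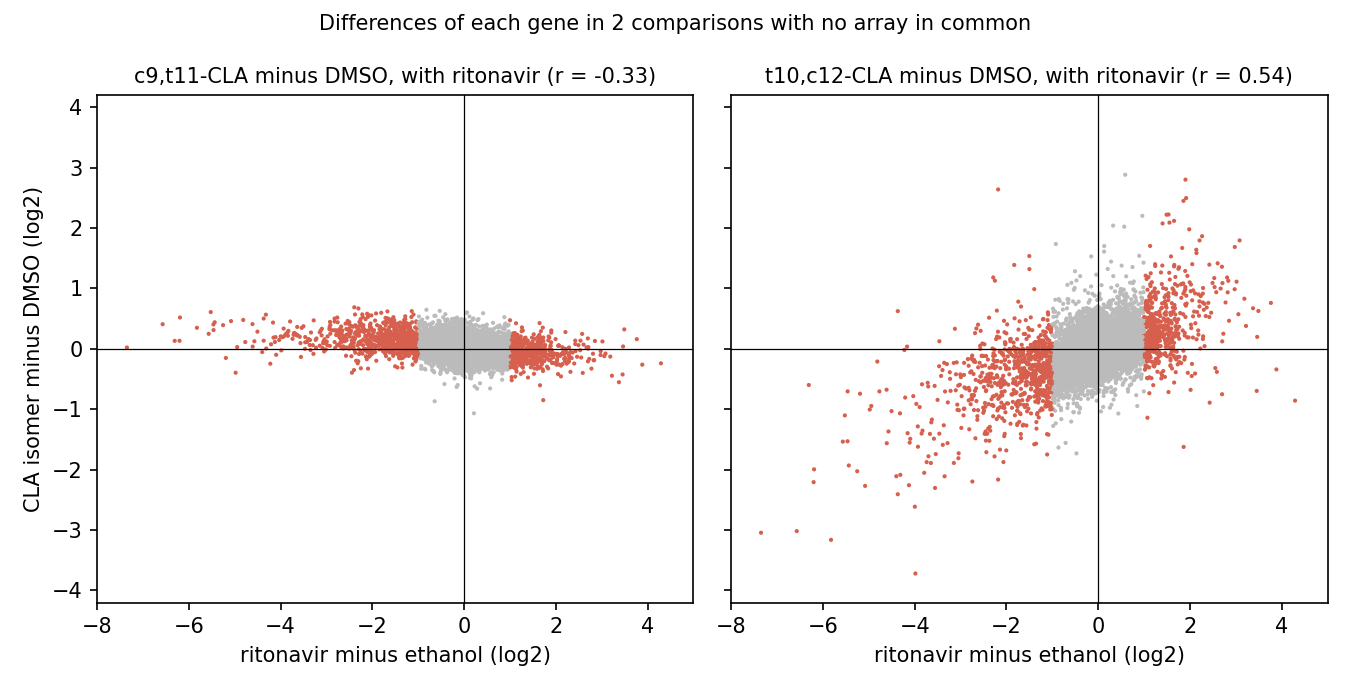
Log2 difference of each detected gene between ritonavir and ethanol (horizontal axis) and between a CLA isomer and DMSO in ritonavir-treated cells (vertical axis), 1 point per gene; red points are at least 2-fold apart between ritonavir and ethanol. Points slope downward for c9,t11-CLA (r = -0.33) within a narrow band and upward for t10,c12-CLA (r = 0.54), across genes that are not independent replicates.

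Across genes the ritonavir difference correlated at -0.33 with the c9,t11-CLA difference, at 0.54 with the t10,c12-CLA difference and at 0.64 with the difference between the isomers. The differences of both isomers from the shared DMSO array correlated at 0.08. Their covariance was 0.00426, against 0.00922 for simulated unchanged arrays with a shared control.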

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

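The tests of RNA degradation, of the experiment or DMSO, of fewer adipocytes and of genes lowered in common were chosen after the results were seen; the tests of an intensity trend were chosen before. The single genes and probe sets named here were chosen after their values were seen.

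A pair of genes was at least 2-fold from ethanol in opposite directions on the arrays with ritonavir; the difference was not tested, since each array stands alone. Ifi27l2a, an interferon-induced gene, differed by -2.09 with ritonavir and by 1.10 with ritonavir and DMSO. Cyp2c23 differed by -1.35 and by 1.28, but its value with ritonavir lay under the detection level, so the first difference is uncertain. In 3 genes the isomers differed from DMSO by at least 1.5-fold in opposite directions, which also was not tested. Hcar2 was 0.61 higher with c9,t11-CLA and differed by -1.10 with t10,c12-CLA, Esco2 by 0.69 and -0.60, and S100a7l2 by -0.66 and 2.02. All 3 values of Esco2, and those of S100a7l2 with DMSO and c9,t11-CLA, lay under the detection level, so opposite directions are not shown for these genes.

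Data outside the comparisons also held signals. A control probe set for the murine B1 repeat was at least 1.30 higher on each of the 4 ritonavir arrays than on both arrays without ritonavir. Among 2396 detected probe sets without a name, 185 were at least 2-fold higher and 87 lower with ritonavir against ethanol, which is 7.72% and 3.63%, whereas named genes gave 4.56% and 6.39%. The shares are not of like units. Every detected probe set counts among the unnamed, but only the probe set with the highest mean counts for a named gene.

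The arrays of ritonavir and of ritonavir with DMSO, which share drug, dose and time, differed at least 2-fold for 608 genes. A trend of the difference with mean expression was argued against, since 607 genes, 343 higher and 264 lower, were 2-fold apart once it was removed, against 351 and 257 before. For RNA degradation in 1 pool, the 3' to 5' difference of the actin control probe sets was 0.19 apart on these arrays. These probe sets lay between 13.93 and 14.60 there, near the top of the scale where values can be compressed, so this test cannot decide. Over the genes 2-fold apart between ritonavir and ethanol, the slope of the ritonavir and DMSO difference was 0.482. Genes picked for a large difference on the first array tend to give a slope below 1. Yet some lists, which were not picked so, also lay nearer to ethanol with DMSO, among them mature adipocyte markers (-2.46 and -0.58) and cholesterol genes (-1.01 and -0.13). The lysosome (0.58 and 0.64) and interferon (0.38 and 0.47) medians were not smaller with DMSO. RNA degradation stays open, as do experiment and vehicle, which cannot be told apart because DMSO was used in the second experiment alone.

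The difference between the isomers ran along the ritonavir difference, with a correlation of 0.64 between comparisons that share no array. An intensity trend was argued against, since the correlation was 0.642 once trends were removed from both. Fewer adipocytes and nothing else would lower adipocyte markers by 1 factor, provided that other cells lack them and the scale is linear. The test used the 9 listed markers that were at least 4-fold lower with ritonavir, detected with c9,t11-CLA and not near the top of the scale there. Their isomer difference lay between -3.51 (Gpd1) and -0.24 (Cd36), with a robust SD of 1.04 (1.25 over all 17 markers detected on an isomer array). The bound was 0.407, from all genes between c9,t11-CLA and DMSO. Whether the proviso holds was not tested, so this spread does not exclude fewer adipocytes alone. Of the 1356 genes 2-fold apart between ritonavir and ethanol, 89.2% had the same sign between the isomers, so t10,c12-CLA and ritonavir may lower the same adipocyte genes. This is a hypothesis found and tested on the same arrays, and a fall in adipocyte number, alone or together with regulation of single genes, stays open.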

How the results depend on the processing

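The lists with ritonavir and DMSO against ethanol, the use of that comparison beside the difference of the ritonavir arrays, and the genes 2-fold from ethanol on both ritonavir arrays were chosen after the data were seen. The count of 558 genes for that comparison was chosen before. No paired analysis was possible because each group had 1 array. Probe set choice, a stricter filter, renewed normalization and lowess removal left all 7 counts within 1.5 times. Renewed normalization could change little, since RMA had already made the distributions equal. No named gene that was 2-fold apart reversed its sign under the mean of probe sets or lowess removal. The stricter filter drops genes and cannot change a kept gene's value. Of the named values tried with these 3 alternatives, 927 moved by less than 0.113 and 114 by more. List medians were tried with these and, for ritonavir against ethanol, also with the ritonavir and DMSO array in place of the ritonavir array. Of these list medians 474 and 87 did so, and 3 reversed. The exchange of arrays accounts for 11, 17 and 2 of them. The 927 include 326 values under the stricter filter, which could not move. The mean of probe sets moved 107 named values by more than 0.113 and left 248 within it. A list median counted as reversed only if it changed sign and had been outside the central range and at least 0.113 from 0. No value was left for 39 named values under an alternative. At 1.5-fold the counts were 3076 for ritonavir against ethanol, 12 for tenofovir, 3138 for ritonavir against tenofovir, 21 for c9,t11-CLA, 876 for t10,c12-CLA, 1002 between the isomers and 1810 between the ritonavir arrays. At 3-fold they were 585, 590 against tenofovir, 0 for c9,t11-CLA, 61 for t10,c12-CLA, 76 and 187. These follow from the threshold. With no filter tenofovir gave 1 and c9,t11-CLA 2, by more dim genes. Ritonavir with DMSO in place of ritonavir gave 558 and the mean of both 858. That mean as control gave 146 for c9,t11-CLA, 121 of them higher, and 71 for t10,c12-CLA. It mixes both experiments, so these counts also carry the difference between the ritonavir arrays, where 608 genes were 2-fold apart. Why the ritonavir arrays differ stays open. Over genes 2-fold from ethanol on both ritonavir arrays the opposite share was 84.2% for c9,t11-CLA in higher genes, and for t10,c12-CLA 28.1% in higher and 24.5% in lower genes; this set is chosen on the DMSO array, which the CLA differences share. On the array with DMSO 17 list medians moved and 2 reversed by this rule, oxidative phosphorylation (0.0065) and ER stress (0.16). Among those that moved, preadipocyte and fibroblast markers (-0.07), extracellular matrix (-0.53), xenobiotic metabolism (-0.01), mitochondrial DNA maintenance (0.13) and bone and cartilage markers (-0.10) also changed sign, from medians inside the central range. The stricter filter left 1 muscle marker, at -0.29, in the isomer comparison.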

Other observations

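The V-ATPase test and the test of an intensity trend were chosen before their results were seen; the comparison of the lysosomal medians on the ritonavir arrays was chosen after, as were the genes named next.

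Some differences were shared by all 4 arrays with ritonavir. In each of them 83 of the 12385 detected genes were at least 2-fold higher and 183 at least 2-fold lower than on both arrays without it. Of the 4 arrays with ritonavir 3 come from the second experiment, and both arrays without ritonavir come from the first. What the 4 share is therefore partly tied to the experiment, and the arrays are not replicates of a ritonavir effect. The higher genes with the largest smallest gap were Mlana (3.58), Mreg (2.74), Gdpd1 (2.10), the efflux pump Abcc4 (2.05), the cholesterol ester hydrolase Nceh1 (2.05) and Cpeb1 (1.95). Mlana, Mreg and Cpeb1 lay under the detection level on both arrays without ritonavir, so their place among these genes is uncertain. The lower genes included Ffar4 (5.30), Ghrh (4.41), Pck1 (3.81), the acute phase genes Lcn2 (3.79) and Hp (3.57), and the hypoxia-induced carbonic anhydrase Car9 (3.14). Pck1 and Car9 lay under that level on all 4 ritonavir arrays, and Ffar4 and Ghrh on some, so these gaps are uncertain too. Igf2 was lower by at least 2.94. Adipoq was not among them, at 14.79 on the ethanol array and 14.67 with c9,t11-CLA. Both values lie near the top of the scale, where they can be compressed, so a difference may be hidden.

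By list, 18 of 21 lysosome and autophagy genes, 15 of 21 interferon-stimulated genes, 12 of 23 ATF4 targets and 19 of 30 proteasome genes were higher on each ritonavir array than on both others, against 28.6% of all detected genes. Lower on each of them were 17 of 18 hypoxia and glycolysis genes, 19 of 22 cell cycle genes and 16 of 19 adipogenic transcription factors, against 22.6%.

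The lysosomal list was higher on both ritonavir arrays against ethanol, with medians of 0.58 and 0.64. An intensity trend was argued against, since the median was 0.53 once the trend was removed. A loss of adipocyte transcripts that raises the share of all others was argued against too, since the medians differed by -0.0604 while mature adipocyte markers differed by 2.08. A wider lysosomal response would raise V-ATPase subunit genes outside the list beyond the upper bound of the central range of random sets on both arrays. The median of 13 such genes was 0.27 at percentile 97.2 for ritonavir and 0.41 at percentile 99.98 for ritonavir with DMSO, so the bound was narrowly missed on 1 array, and whether the response may extend beyond the list stays unproven.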
